A study of Escherichia coli with 6 samples.

How the data were processed

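ChIP-exo maps where a protein sits on DNA: cross-linked chromatin is precipitated with an antibody, and an exonuclease then trims each DNA strand up to the protein, so that the 5′ ends of reads mark the borders of the protected DNA. Per the labels' protocols, Escherichia coli K-12 MG1655 strains carrying a myc-tagged protein were grown at 37 °C to an optical density at 600 nm of about 0.5 in M9 minimal medium with 0.2% glucose or another medium, and the chromatin was precipitated with an antibody against the myc tag. The labels do not say which library came from which medium, so differences between proteins were not separated from possible differences between media. The 3 tagged proteins, YiaU, YqhC and YahB, had 2 libraries each, and the growth protocol speaks of biological replicates. No untagged or mock library was analysed here, so the libraries of the other 2 proteins served as the background for each protein.

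The deposited values are read coverage (signal) at each base of the chromosome on each strand, as whole numbers that are not scaled to depth. Per the submitters' processing notes, the processing involved bcl2fastq and Bowtie, and the sequence named in the deposited files is build NC_000913.2. The treatment of duplicate reads and of reads that match several places, and the settings of the aligner, were not given in the sources used here. In the YiaU and YqhC files, coverage rose and fell in steps that fit reads of 40 nt throughout, so that the start of each read could be recovered. The YahB files did not have this form, and read starts were not recovered for them. This difference in read processing coincides with the YahB group and could not be separated from it.

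Total coverage was 194 and 191 Mb in the YiaU libraries, 213 and 187 Mb in the YqhC libraries and 145 and 163 Mb in the YahB libraries. With 40-nt reads this corresponded to 4.85 and 4.77 M reads for YiaU and 5.33 and 4.67 M reads for YqhC (M, mega). Each occupied start position held on average 9.45 and 10.99 reads in YiaU, and 5.99 and 5.83 in YqhC. Reads that repeat the same molecule and reads of different molecules that end at the same border were not told apart, so the number of independent molecules is not known.

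Mean coverage was taken over 46396 windows of 100 bp, both strands together, and divided by the median window of the library; these relative values are called levels. The median window held 23.3, 22.9, 35.2, 30.7, 26.5 and 32.4 reads of coverage in YiaU replicates 1 and 2, YqhC replicates 1 and 2, and YahB replicates 1 and 2. Because the unit is coverage, the test set aside for such values before the data were examined was used: limma 3.58.1 in R 4.3.3, on log2(level + 0.25), with the mean-variance trend and robust variance estimation, 3 group means, and the contrast of each protein with the mean of the other 2. Fold changes are on this log2(level + 0.25) scale and understate the change of low windows. A filter on windows with a mean level under 0.1 removed none. A window was called when the Benjamini-Hochberg adjusted p was under 0.05, the log2 fold change was at least 2, and both libraries of the protein exceeded all 4 others, in total and on each strand separately. Called windows 100 bp or less apart were merged into regions, and the window with the largest fold change is the summit. Regions within 5 kb of each other were counted as a locus. Levels are given as mean ± SD of 2 replicates at the summit window.

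The rule for naming, also fixed beforehand, took up to 10 regions per protein with the largest log2 fold change at the summit, and the 10 windows with the highest mean over the 6 libraries among those at 5 times the library median or more in all 6. Any other position named in the text was chosen after its values were seen. Read borders were the positions with the most read starts on each strand near the summit, and the strand offset was the distance between the highest forward and the highest reverse coverage within 100 bp of the summit.

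The model was tested on simulated data with 200 changed windows among 46396 for each protein. All windows simulated at a log2 change of 3 or 4 were called for YiaU, YqhC and YahB, with 0 false calls. The simulated windows had no strands, so the rule on each strand was not part of this test. Apart from the changed windows, all proteins were given the same mean in each window, and windows varied independently. The simulation therefore cannot show how many calls arise from differences in profile between proteins. At a log2 change of 1.5, which lies under the threshold of 2, 5.97%, 1.49% and 2.99% were called for YiaU, YqhC and YahB.

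The table of genes used here belongs to another assembly, ASM584v2, and positions were not converted between builds. Regions are therefore given by position, without the gene, promoter or operon they lie in. The planned tests of promoters, of gene lists (the neighbourhoods of yiaU, yqhC and yahB and sets of functional genes), and of coverage at the 3′ ends of the tagged genes need gene positions in the build of the files and were not run.

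Alternatives planned before the data were examined were the scaling, the pseudocount, window size and phase, thresholds, the strand rule, the background proteins, a replicate block, and leaving out each library. Cyclic loess scaling, a local 3-kb background, single-protein backgrounds and keeping 1 read per start position were added after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the remaining steps.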

Results

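Binding of 3 candidate transcription factors of Escherichia coli K-12 MG1655 was mapped by ChIP-exo, to find the sites on the chromosome where each protein sits. YiaU and YahB belong to the LysR family of regulators. YqhC is an AraC-family activator of the neighbouring aldehyde reductase genes yqhD and dkgA. Each protein carried a C-terminal myc tag and had 2 libraries. Coverage of the 4639675-bp chromosome totalled 145 to 213 Mb per library. Bases without any read made up 7.18% and 10.8% of the chromosome in the YiaU libraries, 0.423% and 0.721% in the YqhC libraries, and almost none in the YahB libraries. Over 46396 windows, log2 levels correlated with Pearson's r of 0.774 to 0.862 between libraries of the same protein and 0.568 to 0.653 between proteins; windows are not independent replicates. Away from peaks, the YiaU replicates shared 1.87 times as many read starts as independent placement would give, close to the 1.755 to 1.774 times of the other pairs of YiaU and YqhC libraries, so the replicates of these proteins were counted as separate libraries. The YahB replicates, for which read starts were not recovered, were counted as separate on the basis of their labels; 499 and 132 windows stood at 5 times the median or more in them.

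The first comparison asked where YiaU coverage stood above that of YqhC and YahB. YiaU was enriched in 117 regions that together covered 69.6 kb and fell into 91 loci. Of these regions, 7 overlapped the long forward-strand blocks described under Other observations. They were counted as separate regions, although whether those blocks share reads of repeated sequence was left open. The count was 65 when both other proteins had to be exceeded separately, 72 with a pseudocount of 1, 56 with scaling to the library total and 44 with a local 3-kb background. The region with the largest fold change, at 1997501 to 1998500, reached a level of 37.6 ± 0.204 (SD, n = 2) in YiaU against 1.56 ± 0.384 in YqhC and 0.882 ± 0.0322 in YahB. A level of 1 is the median window of a library. The second, at 2530301 to 2531500, reached 52.6 ± 7.19 against 2.89 ± 0.0731 and 1.51 ± 0.0979. Most regions were short: 88 were at most 500 bp wide and 22 at least 1000 bp, with a median width of 200 bp and a maximum of 3700 bp.

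Among the 10 YiaU regions with the largest fold changes, log2 fold changes ranged from 4.73 (SE 0.21, limma adjusted p = 2.09e-06) at 1997501 to 3.72 (SE 0.46, limma adjusted p = 0.000229) at 169701. Several were long. Regions at 2871101 to 2874500 (22.2 ± 0.116 in YiaU), 2538101 to 2541600 (27.0 ± 1.70) and 4011101 to 4013400 (22.6 ± 0.121) spanned 2300 to 3500 bp, with levels from 0.478 to 2.76 at these summits in the other proteins. The region at 2889601 to 2890100 reached 29.5 ± 0.528 in YiaU, against 3.22 ± 0.116 in YqhC and 1.19 ± 0.282 in YahB.

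The other 4 of these 10 YiaU regions were also enriched in the background libraries, at 3 times the median or more in all 4. The region at 169701 to 170100 reached 231.5 ± 0.833 in YiaU, 37.7 ± 1.34 in YqhC and 8.26 ± 3.50 in YahB. The regions at 3421401 to 3424200, 226201 to 229100 and 3942201 to 3945200 reached 103.7 ± 3.003, 69.2 ± 2.76 and 136.8 ± 0.587 in YiaU, and 6.70 ± 2.65, 5.55 ± 2.61 and 7.79 ± 3.74 in YahB. In YqhC the first and the last reached 4.42 ± 0.286 and 11.9 ± 0.411, and that at 226201 stood at 4.34 and 3.67 in the 2 replicates. The calls at 169701 and 3942201 were lost after cyclic loess scaling, at log2 fold changes of 1.00 and 1.49, and with 1 read per start position against YqhC alone, at 1.36 and 1.72; that at 226201 was lost after cyclic loess scaling, at 1.96. Keeping 1 read per start position caps coverage at 40 reads per base and strand, so it can also shrink real differences at strong peaks. Of the 10 named YiaU regions, 6 lost their call against a local 3-kb background, which takes out broad enrichment. Over the whole regions, the forward strand held 92.5%, 86.0% and 78.5% of the coverage at 3421401, 226201 and 3942201, and 51.1% at 169701. At their summit windows it held 49.2%, 94.3%, 57.2% and 58.1%. The regions at 3421401, 226201 and 3942201 overlap the long forward-strand blocks described under Other observations.

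Across all 117 YiaU regions, the median summit level was 13.98 in YiaU, 2.89 in YqhC and 1.36 in YahB, and fold changes ran from 4.01 to 26.6. At 52 summits both YqhC libraries also stood at 3 times their median or more, and at 40 both stayed under 2 times. Both YahB libraries stayed under 2 times at 72 summits. Among all windows, 4387 were higher and 1455 lower in YiaU at a limma adjusted p under 0.05. With scaling to the library total these became 2369 and 12084, with the median of all windows at a log2 change of -0.42, and with scaling to the 75th percentile window 3063 and 4066, with the median at -0.22. After cyclic loess scaling, which was added after seeing the data and removes differences that follow the mean level of a window, 21 regions were called and 17 of the 117 overlapped them. The same scaling gave 23 YqhC regions.

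**Figure D1:**
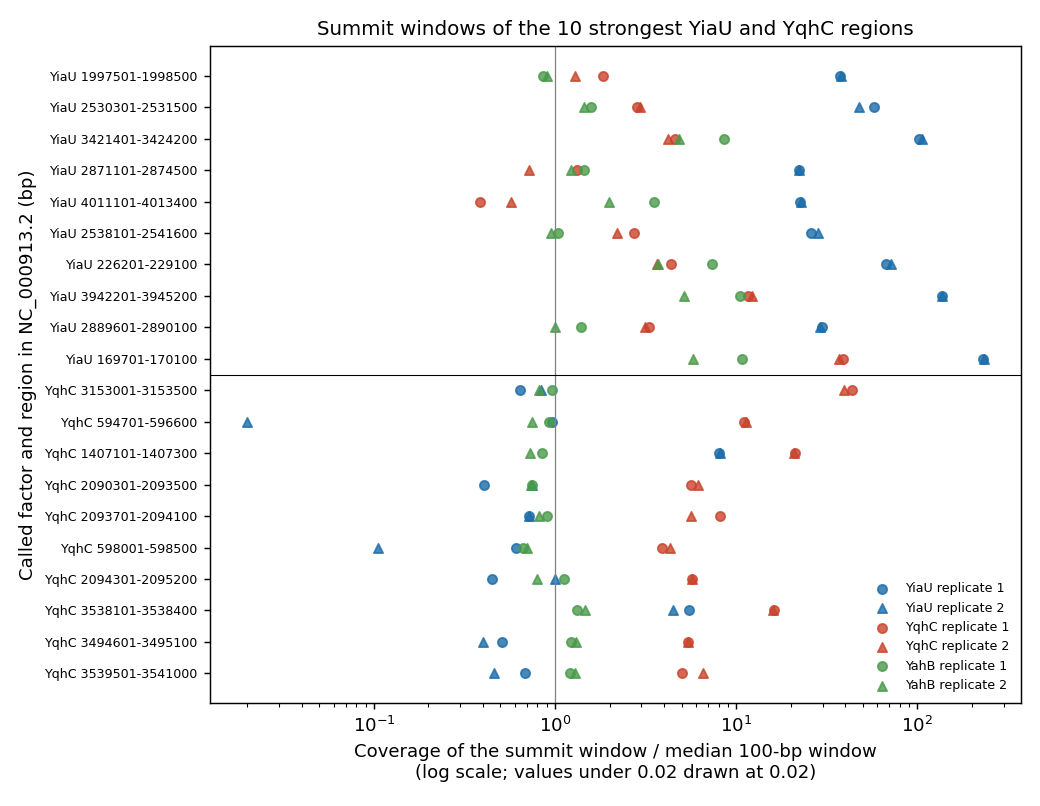
Level of the summit window in each of the 6 libraries for the 10 YiaU and 10 YqhC regions with the largest fold changes. The horizontal axis is coverage divided by the median 100-bp window of the library, on a log scale, with values under 0.02 drawn at 0.02; circles are replicate 1, triangles are replicate 2, and colours are the proteins. YiaU replicates lie to the right of the 4 others in the upper 10 regions and YqhC replicates in the lower 10, and the other libraries reach from below 1 to 38.7.

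The second comparison asked the same of YqhC. YqhC was enriched in 28 regions, 12.7 kb in all, that fell into 15 loci. The count was 14 when both other proteins had to be exceeded separately, 6 with a pseudocount of 1 and 3 with the local 3-kb background. The region at 3153001 to 3153500 stood out with a level of 41.5 ± 2.99 (SD, n = 2) in YqhC against 0.740 ± 0.142 in YiaU and 0.890 ± 0.106 in YahB, a log2 fold change of 5.30 (SE 0.19, limma adjusted p = 3.87e-07). It was the largest fold change of any region in the 3 comparisons. Its forward read border lay at 3153245 in both YqhC replicates and its reverse border at 3153350 and 3153348, so that the borders enclosed 106 and 104 bp. Borders lay within 5 bp of each other in both replicates in 2 of the 20 named regions of YiaU and YqhC. These were 3153001 of YqhC and 169701 of YiaU. Borders of the regions not named were not tallied, and some of those regions met the same limit. In YiaU, borders lay at 3889535 and 3889580 in both replicates for region 3889301, and at 1039419 and 1039463 for 1039401. Region 1608701 of YqhC met it as well. At 3153001 the highest forward and reverse coverage lay 55 and 56 bp apart.

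**Figure D2:**
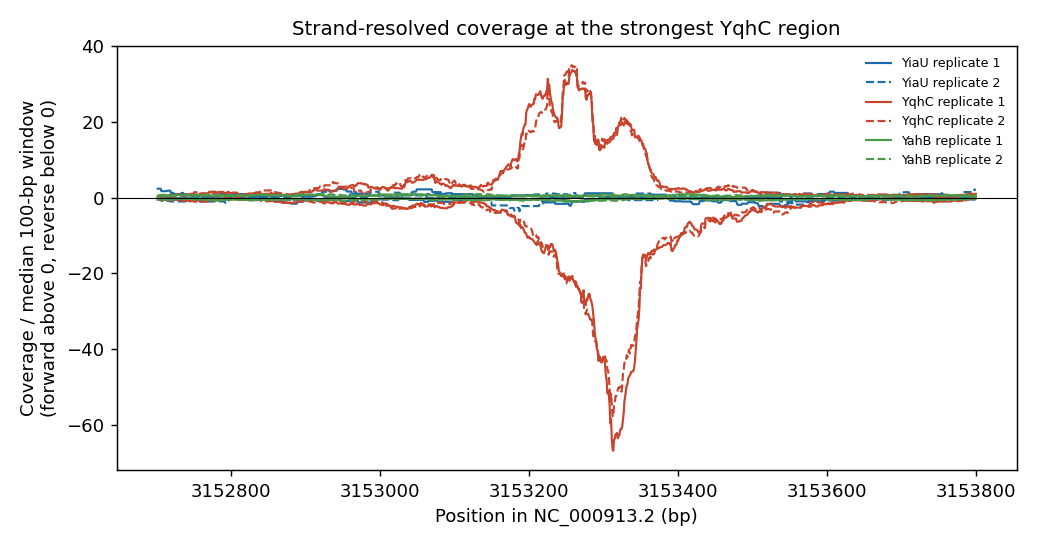
Coverage around the YqhC region at 3153001 to 3153500, forward strand above 0 and reverse strand below 0, divided by the median 100-bp window of each library. Each line is a library, solid for replicate 1 and dashed for replicate 2; both YqhC replicates rise on both strands with summits 55 and 56 bp apart, while the 4 other libraries stay near the axis.

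The remaining YqhC regions were weaker and often clustered. The 5 regions between 594701 and 601300 formed a locus of 6.6 kb whose strongest region, 594701 to 596600, had a log2 fold change of 3.89 (SE 0.46) and levels of 11.2 ± 0.152 in YqhC, 0.483 ± 0.683 in YiaU and 0.833 ± 0.124 in YahB; its summit held no coverage in YiaU replicate 2. Another named region of this locus, 598001 to 598500, reached 4.10 ± 0.308 in YqhC. The 3 regions between 2090301 and 2095200 covered 4500 of 4900 bp, gaps between merged windows included. Their summit windows had levels of 5.71 to 6.86 in YqhC and under 1 in the means of the others. Regions at 3494601 to 3495100 and 3539501 to 3541000 reached 5.44 ± 0.00410 and 5.78 ± 1.09 in YqhC, 0.456 ± 0.0787 and 0.570 ± 0.154 in YiaU, and 1.26 ± 0.0549 and 1.25 ± 0.0611 in YahB. Both calls were lost against YahB alone, at log2 fold changes of 1.92 and 1.997, when both proteins had to be exceeded separately, and with a pseudocount of 1, at 1.83 and 1.84.

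Some YqhC regions carried YiaU coverage as well. The region at 1407101 to 1407300 reached 21.0 ± 0.307 in YqhC, 8.11 ± 0.0869 in YiaU and 0.790 ± 0.0847 in YahB, and that at 3538101 to 3538400 reached 16.1 ± 0.0738, 4.99 ± 0.733 and 1.39 ± 0.104. Both lost their call when YqhC was set against YiaU alone, at log2 fold changes of 1.35 and 1.65, which became 0.32 and 0.81 with 1 read per start position. That setting caps coverage on each strand and can shrink real differences at strong peaks, so these drops were not traced to duplicate reads. Of the 28 summits, 5 stood at 3 times the median or more in both YiaU libraries and 18 under 2 times, and 26 were under 2 times in both YahB libraries.

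Without YqhC replicate 2, 4 regions were called, and without replicate 1, 25, with the lone library assumed to vary like the other groups. Of the 28 regions, 3 and 15 overlapped those calls. The 8 named YqhC regions not called without replicate 2 had log2 fold changes of 2.25 to 3.87 there and missed the threshold on p, at limma adjusted p of 0.0507 to 0.121. Without replicate 1, 3 named regions missed it, at log2 fold changes of 2.49 to 3.90 and limma adjusted p of 0.0704 to 0.115; 594701 was among those lost in both cases. With the local 3-kb background, 8 named YqhC regions lost their call, and 3153001 and 1407101 did not. Among all windows 690 were higher and 902 lower in YqhC at a limma adjusted p under 0.05, and 1315 and 928 with scaling to the library total.

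The third comparison asked where YahB coverage stood above the others. For YahB 0 regions were called. In limma 135 windows were higher and 3435 lower in YahB at an adjusted p under 0.05, and 2522 were higher at an unadjusted p under 0.05, but the largest log2 fold change of any window that met the other rules was 1.59, under the threshold of 2. With scaling to the library total the split was 4013 higher and 2091 lower, with the median of all windows at a log2 change of 0.33, and with the 75th percentile window 1011 and 2264, with the median at 0.22. With a threshold of 1 in place of 2 there were 75 regions of 76 windows, whose median level was 1.23 in YahB and 0.462 in the others; 4 of the windows reached a mean of 2 in YahB.

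Among these windows, chosen after their values were seen, that at 333701 to 333800 had a level of 2.28 ± 0.451 (SD, n = 2) in YahB, 0.674 ± 0.244 in YiaU and 0.718 ± 0.344 in YqhC, a log2 fold change of 1.44 (SE 0.28, limma adjusted p = 0.00808). The windows at 3945401 and 3981101 had 2.68 ± 0.535 and 2.79 ± 1.06 in YahB, against means of 0.810 to 1.22 in the other proteins. The simulated windows at a log2 change of 3 or 4 were all called for YahB. That simulation left out the rule on each strand and differences in profile between proteins. Log2 changes between 1.5 and 3 were not simulated.

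Enrichment common to the 3 proteins was described without a test. At 5 times the library median or more stood 1737 and 1751 windows in YiaU, 841 and 876 in YqhC, and 499 and 132 in YahB. In all 6 libraries 119 windows passed, in 14 regions, and without YahB replicate 2 the number was 295. The windows that passed in both libraries numbered 1524 for YiaU and 772 for YqhC, of which 572 were common where 25.4 would be expected of independent lists. All 132 windows of YahB were among those of YiaU, and 119 among those of YqhC.

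The window at 3889501 to 3889600 had the highest level in each of the 6 libraries: 1364 ± 22.1 (SD, n = 2) in YiaU, 217.9 ± 6.13 in YqhC and 63.8 ± 36.7 in YahB, where the replicates stood at 89.8 and 37.9. It held 1.66% and 1.62% of all coverage in the YiaU libraries. The same window is the summit of a called YiaU region, 3889301 to 3889800, with a log2 fold change of 3.59 (SE 0.80, limma adjusted p = 0.0120). That region is among 13 of the 117 YiaU regions that stood at 3 times the median or more in all 4 other libraries. The neighbouring windows at 3889401 and 3889601 were among the 10 highest too, with means over the 6 libraries of 104.4 and 85.3, as was 169801 with 92.5. The other 6 of the 10 lay between 2724601 and 2725100 and between 3422401 and 3422600, with means of 56.5 to 72.3. These means follow YiaU, whose levels were the highest. Common regions with higher levels in YqhC than in YiaU, named here after their values were seen, included 3980401 to 3980900 (median levels of 27.5 in YqhC, 22.0 in YiaU and 9.23 in YahB) and 2816301 to 2816500 (19.8, 16.4 and 8.24). Of the 14 common regions, 6 had at least 90% of their coverage on the forward strand and 0 on the reverse strand.

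**Figure D3:**
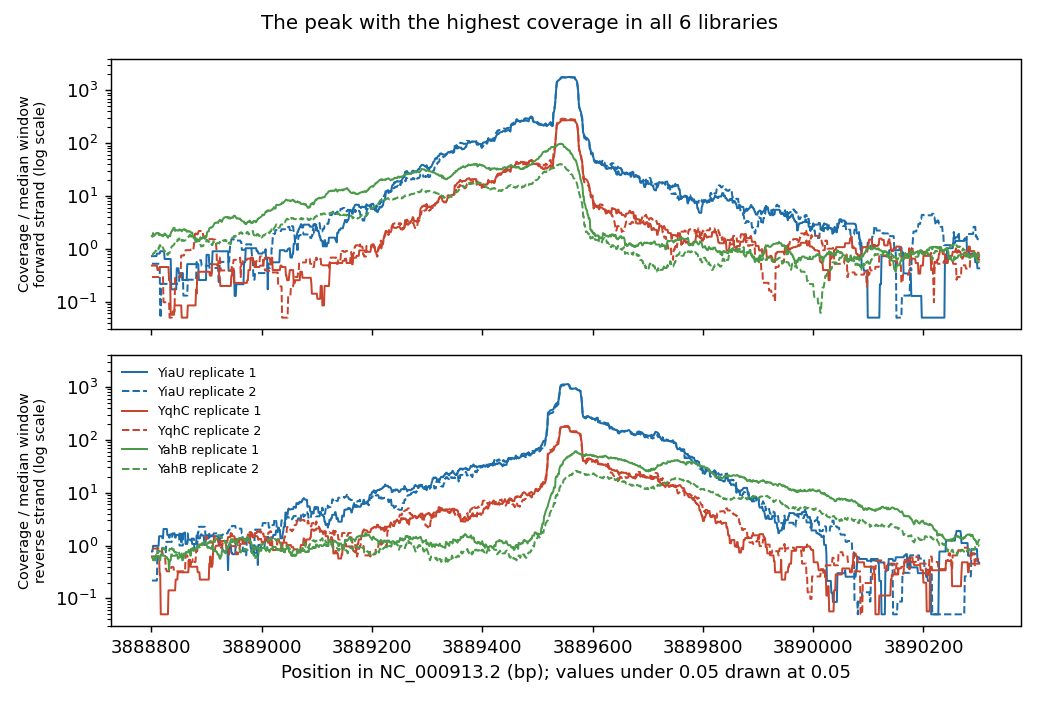
Coverage around the window at 3889501 to 3889600 in the 6 libraries, forward strand in the upper panel and reverse strand in the lower panel, divided by the median 100-bp window of each library, on a log scale with values under 0.05 drawn at 0.05. Each line is a library, solid for replicate 1 and dashed for replicate 2; all 6 rise at the same place, highest in YiaU (window level 1364) and lowest in YahB (63.8).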

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

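Scaling by cyclic loess, a local 3-kb background, single-protein backgrounds and 1 read per start position were chosen after seeing the data; the other alternatives were planned. Regions are higher by rule, so no region count can change direction, while the split of all windows into higher and lower moved with the scaling as given in the report. The causes of the changes below were not tested except where the setting itself is stricter or looser. The 117 YiaU regions became 56 with library totals, 74 with the 75th percentile window, 72 with a pseudocount of 1, 193 in 50-bp windows, 663 and 29 at log2 thresholds of 1 and 3, 65 when both other proteins had to be exceeded separately, 21 with cyclic loess, 44 with the 3-kb background, 275 against YahB alone, and 73 against YqhC alone with 1 read per start position. The 28 YqhC regions became 6 with a pseudocount of 1, 46 and 16 in windows of 50 and 200 bp, 125 and 3 at log2 thresholds of 1 and 3, 14 against both separately, 3 with the 3-kb background and 111 against YahB alone. YahB had 1 region with a pseudocount of 0.05, 1 in 50-bp windows, 1 with the 3-kb background, 75 at a log2 threshold of 1, 1 against YqhC alone and 6 against YiaU alone. The 119 windows enriched in all 6 libraries became 380 and 13 at 3 and 10 times the median, and 59 in 200-bp windows. Leaving out each library gave 109 to 146 YiaU regions, 4 to 36 YqhC regions (4 without YqhC replicate 2), 0 to 0 YahB regions, and 119 to 295 common windows (295 without YahB replicate 2). Other alternatives stayed within 1.5 times of the count: 16 of 27 for YiaU and 18 of 27 for YqhC, with 20 of 26 at 0 for YahB; the filter on low windows removed nothing and tests nothing.

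The replicate number as a block gave 117 YiaU, 28 YqhC and 0 YahB regions. Deviations of same-numbered libraries were uncorrelated (-0.00529, -0.0134 and -0.00996), so the libraries share only a number.

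Over the alternatives, the 10 named YiaU regions kept their call in 259 cases and lost it in 11, and the 10 YqhC regions kept it in 227 and lost it in 43. The regions at 1997501, 2530301 and 2889601 of YiaU and 3153001 of YqhC were called in 27 of 27. Some of these settings could not end a named call. A log2 threshold of 1, no rule on each strand and no filter do not make the rule stricter. A limma adjusted p under 0.01 was already met by all named regions, and a log2 threshold of 3 by the 10 named YiaU regions. Part of the kept calls was therefore fixed in advance. The 3-kb background, which subtracts broad enrichment by construction, ended 14 named calls, leaving out YqhC replicate 2 ended 8, at log2 fold changes of 2.25 to 3.87 and through the threshold on adjusted p (limma, 0.0507 to 0.121), and a log2 threshold of 3 ended 8. Promoter and gene list alternatives, and those for count values, were not run.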

Other observations

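The test of block profiles and that of the chromosome trend were set before their results were seen; the others, including the wording that limits the duplicate reads to the whole cause, were chosen afterwards.

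Coverage rose and fell slowly along the chromosome in all 6 libraries. A cosine fitted to medians of 100-kb bins peaked between 3917 and 4025 kb and was lowest between 1597 and 1705 kb, with a ratio of maximum to minimum of 1.37 and 1.37 in YqhC, 1.506 and 1.504 in YiaU, and 1.65 and 1.71 in YahB. The cosine has 1 maximum and 1 minimum by construction, so only their places could differ between libraries. Its r squared was 0.55 and 0.54 in YiaU, 0.68 and 0.67 in YqhC, and 0.88 and 0.94 in YahB. The maxima lay at most 108 kb apart. This is consistent with gene dosage in growing cells, higher near the replication origin, as a hypothesis, since the position of the origin in this build was not used.

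YiaU had several times more called regions than YqhC, 117 against 28. Stacks of duplicate reads as the whole cause were examined by keeping 1 read per start position. That step caps coverage at 40 reads per base and strand. YiaU had fewer occupied start positions (513167 and 434169) than YqhC (889676 and 801601). After scaling to the median, levels could therefore reach higher in YiaU, so the values below leave this cause undecided. Of the 96 YiaU regions called against YqhC alone, 60 (62.5%) overlapped a region called with 1 read per start position, and 36 did not. The 95% exact binomial interval of 52.0 to 72.2% is for counting error only. It takes regions as independent and holds no variation between libraries. With 1 read per start position, 73 YiaU regions were called against YqhC alone and 24 YqhC regions against YiaU alone. With all reads these counts were 96 and 34. In the original test 36 YiaU and 18 YqhC regions had all 4 other libraries under 2 times the median. All 4 stood under their median in 1 of the 117 YiaU regions and in 8 of the 28 YqhC regions. The excess was not seen after cyclic loess scaling, with 21 YiaU and 23 YqhC regions (a ratio of 0.913), and was smaller with library totals, 56 and 30, but larger with the 3-kb background, 44 and 3, with a pseudocount of 1, 72 and 6, and at a log2 threshold of 3, 29 and 3; under cyclic loess the log2 fold changes at 1997501 and 2889601 fell from 4.73 and 3.74 to 3.56 and 2.41. A steeper shared profile in the YiaU libraries and more binding by YiaU cannot be told apart, because that scaling also takes out real enrichment that follows the level, and no untagged library was analysed here.

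The peak at 3889501 to 3889600 was the highest in every library. Carry-over of YiaU molecules would bring the same share of YiaU coverage to each site, and at this window YqhC stood at 16.0% of YiaU. Of the 110 windows at 50 times the median or more in both YiaU libraries, 85 (77.3%) lay below that share in both YqhC libraries, which argues against carry-over as the source of the YqhC peak. Carry-over into the YahB libraries, where this window stood at 4.68% of YiaU, was not tested and stays open. A site bound in any tagged strain, by the antibody or by another protein, also stays open and was not tested.

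Coverage was almost confined to the forward strand in 7 blocks of 4600 to 5300 bp, with 86.9 to 94.97% of it forward; 7 YiaU regions and 9 of the 14 regions enriched in all libraries overlapped them. The gene table of assembly ASM584v2 lists 7 copies each of rrl and rrs, the genes of the large- and small-subunit ribosomal RNAs, but the blocks were not matched to genes. If reads of 7 near-identical copies were shared by 2 blocks of one orientation and 5 of the other, the level of the former would be 2.5 times that of the latter, and the 2 highest blocks (2724101 and 3421701) stood at 2.55 and 2.58 times the others in YahB, 2.44 and 2.44 in YqhC, and 2.16 and 2.13 in YiaU. Repeated sequence also predicts profiles that correlate above 0.9 between blocks of the same level; the median was 0.573 in YahB replicate 1, where it was first computed (highest of the control stretches 0.545), and 0.484 between blocks of different level there, while the libraries examined after that value was seen gave 0.542 in YahB (control at most 0.514), 0.771 and 0.767 in YqhC (0.647 and 0.650) and 0.890 and 0.884 in YiaU (0.573 and 0.580). No median reached 0.9 and those between blocks of the same level were above 0.5, so this test leaves repeated sequence open, and the ratio is consistent with shared reads only as a hypothesis formed after the levels were seen.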
